A study of Mus musculus with 8 samples.

How the data were processed

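Total RNA of mouse intestine and colon with and without Nanog overexpression was measured on 8 Illumina bead arrays, 4 groups of 2. Per the labels, biotin-labelled cRNA was hybridized, and the submitters' processing notes name BeadStudio 3.2, RMA and lumi, with the order and settings not given in the sources used here. The deposited table without normalization holds for each of 25697 probes the mean bead signal as an intensity, neither background-subtracted nor scaled between arrays. Beside each intensity the deposited table gives a detection p-value, the rank of the probe among the array's negative control beads, in 798 steps. The authors' normalized values are on a log2 scale, hold the same quantiles on all 8 arrays and rank the probes of each array as the intensities do.

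The intensities were background-corrected with limma 3.58.1 in R 4.3.3 by the normal-exponential model, with negative controls inferred from the detection p-values and an offset of 16, then quantile-normalized and taken to log2. A probe entered the tests with a detection p-value under 0.01 on both arrays of at least 1 group, which 12064 probes met. Gene symbols came from the array's annotation through Entrez identifiers and assembly GRCm38.p6, 1719 probes had none, and the probe with the highest mean stood for each of the 8607 genes tested. Where a group was below background on both its arrays, folds are given as lower bounds.

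A linear model with a mean per group was fitted to all 8 arrays, with limma's moderated test (4 residual degrees of freedom, 3.07 prior degrees of freedom, prior SD 0.292). The contrasts were Nanog against no Nanog in intestine, in colon and on average of the tissues, the difference of these effects (colon minus intestine), and colon against intestine without Nanog. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the 8607 genes. Before the data were examined, 34 gene lists of cell types, pathways and stress responses, the tests and most alternative settings were fixed. Lists were tested with camera at a preset correlation of 0.01, camera with an estimated correlation, and fry, adjusted over the 34 lists.

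The genes named are Nanog, a fixed panel (Cdx2, Klf4, Lgr5, Ascl2, Olfm4, Muc2, Mki67, Myc, Hes1 and Notch1), the called genes with the 10 largest rises and falls in each tissue and between tissues, the 5 largest in each direction on average, the 5 smallest p in each direction where none was called, and list members with the smallest p or a call. From these the text prints examples. On simulated data with the same design, changes of 2 log2 units were recovered for 78.2% of genes in intestine, 80.8% in colon, 92.8% on average and 37.6% for the difference, with 5.1% to 6% false calls. A list of 12 genes shifted by 0.7 was called in 100% of runs with the preset and 70% with the estimated correlation. Both simulations drew each gene independently, so they do not show how often calls are false where genes vary together.

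The alternatives were the authors' values, no background correction, an offset of 50, median scaling, cyclic loess, no detection filter, detection on all 8 arrays, the mean of a gene's probes, the replicate number as a block, a variance trend with robust estimation, array weights, only the 4 arrays compared, a 2-fold minimum, and each array left out. Added after the data were seen were a fit without the 2 Nanog arrays highest in pancreatic genes and a fit with the pancreatic list's mean as a covariate. No sample was left out of the main tests.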

Results

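RNA of mouse intestine and colon, with or without overexpression of Nanog, was measured on 8 Illumina bead arrays, which read each transcript by the brightness of beads carrying a matching probe. Nanog is a homeobox transcription factor of pluripotent cells. The samples form 4 groups of 2 arrays each, intestine without Nanog, intestine with Nanog, colon without Nanog and colon with Nanog, and the labels call the 2 arrays of a group biological replicates. How Nanog was expressed, for how long, and whether intestine and colon came from the same animals is not given in the sources used here. Between 10652 and 11993 of the 25697 probes per array were above background at a detection p-value under 0.01. The median signal was 84.6 on replicate 2 of intestine with Nanog, the dimmest array, and between 96.2 and 107.7 on the other arrays. Replicates of a group correlated over the 8607 tested genes with r = 0.902 in intestine without Nanog, 0.915 in intestine with Nanog, 0.967 in colon without Nanog and 0.965 in colon with Nanog. In intestine, arrays of the same number resembled each other at least as much as arrays of the same group, with r = 0.949 between the replicates 1 and 0.925 between the replicates 2 of the groups without and with Nanog. The median SD of a gene between replicates was 0.291 log2 units in intestine without Nanog and 0.234 with Nanog. In colon it was 0.205 without and 0.143 with Nanog. Each SE below rests on a single spread per gene pooled over all 4 groups, so it is not a tissue's own. The precision of every value below is limited by the 2 arrays per group.

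The overexpressed gene itself was read by a single probe, which stayed below background on all 8 arrays, with detection p-values from 0.172 to 0.817. Its signal was 92.2 ± 1.80 (SD, n = 2) in intestine without Nanog and 83.7 ± 4.43 (SD, n = 2) in intestine with Nanog. In colon it was 91.5 ± 4.35 (SD, n = 2) without Nanog and 86.7 ± 2.47 (SD, n = 2) with Nanog. The position of this probe relative to the overexpressed transcript is not known here, so the probe checks nothing about the labels, and it was not above background in any group and entered no test.

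Genes of pancreatic acinar cells, the cells that make digestive enzymes, differed widely between arrays of the same group. The mean normalized log2 intensity of the 13 tested genes of this list was 5.36 on replicate 1 and 10.31 on replicate 2 of intestine without Nanog, and 5.61 and 14.29 on replicates 1 and 2 of intestine with Nanog. In colon it was 4.82 and 7.07 without Nanog and 7.54 and 13.77 with Nanog. The list stood higher with Nanog on average of the tissues, by a median of 3.53 log2 units with an adjusted p of 0.00405 by the gene set test camera at its preset correlation. The adjusted p was 0.629 with an estimated correlation, and 0 of the 13 genes passed the test singly. The arrays with the highest values, replicate 2 of intestine with Nanog and replicate 2 of colon with Nanog, enter every comparison with Nanog below.

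**Figure D1:**
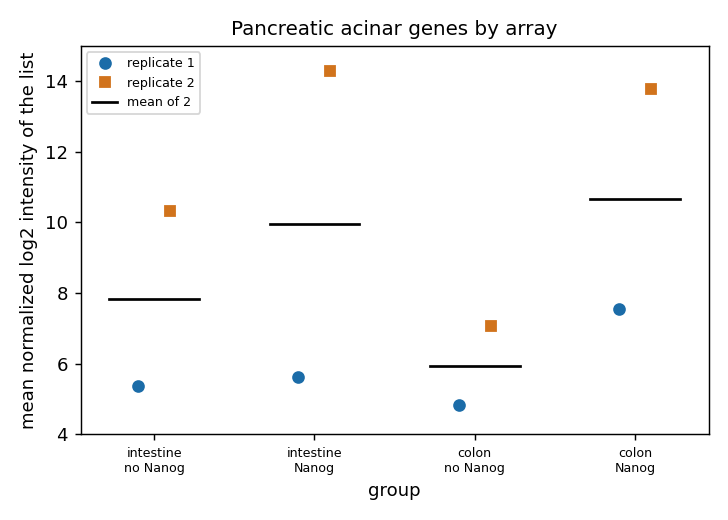
Mean normalized log2 intensity of the 13 tested pancreatic acinar genes on each of the 8 arrays, by group (points, replicate 1 as circles and replicate 2 as squares; bars, mean of the 2 arrays). Replicate 2 lies above replicate 1 in each of the 4 groups, and the highest arrays are replicate 2 of intestine with Nanog at 14.29 and replicate 2 of colon with Nanog at 13.77.

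The comparison of intestine with and without Nanog asks which transcripts change with Nanog in this tissue. 14 of 8607 genes passed an adjusted p of 0.05 in limma's moderated test, 12 of them higher and 2 lower with Nanog. The largest rises were those of Csrp1, which encodes a LIM-domain protein of the actin cytoskeleton, by 5.42 ± 0.30 log2 units (SE, adjusted p = 0.00310), and Fkbp5, a glucocorticoid-induced chaperone partner, by 5.36 ± 0.40 (SE, adjusted p = 0.00540). Angptl4, a secreted inhibitor of lipoprotein lipase, rose by 4.36, Eif4ebp3, a translation repressor, by 3.64, G6pc, the catalytic subunit of glucose-6-phosphatase, by 3.46, and Ddit4, an inhibitor of mTORC1 signalling, by 3.36. Eif4ebp3, like Csrp1, was above background on 1 of the 2 arrays without Nanog. Depp1 rose by 3.01 and the sulfotransferase Sult1a1 by 2.95. Tor1aip2 and Tom1l2 were below background in both controls and stood at least 6.96-fold and at least 7.86-fold higher with Nanog, adjusted p = 0.00407 and 0.0310. Such a bound takes, on each array, the higher of the lowest signal above background and the probe's own value. The falls were those of Ky, with a log2 change of -2.71, and of Pdrg1, which went below background on both Nanog arrays, at least 2.58-fold lower (adjusted p = 0.00942). In all 14 genes the Nanog arrays lay wholly above or wholly below the control arrays, which chance gives for 33.3% of genes and which held for 32.5% of the genes tested. The comparison called 71 genes, 19 higher and 52 lower, without control replicate 1, 22 without control replicate 2, 2 without Nanog replicate 2 and 9 without either colon control array, and of the 14 genes Csrp1 and Ddit4 passed whichever single array was left out. The 4 intestine arrays alone called 0 genes, with 442 at an unadjusted p under 0.05, and scaling arrays to a common median split the calls into 9 higher and 3 lower. Without replicate 2 of both Nanog groups, the arrays highest in pancreatic genes, limma called 0 genes in intestine, with 402 at an unadjusted p under 0.05, a setting chosen after seeing the data.

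In colon the comparison called 19 of 8607 genes, 13 higher and 6 lower with Nanog. Arg2, a mitochondrial arginase, rose most, by 4.78 ± 0.42 log2 units (SE, adjusted p = 0.0113), followed by Csrp1 with 4.43 ± 0.30 (adjusted p = 0.00531) and Fkbp5 with 3.96 ± 0.40 (adjusted p = 0.0212). The bestrophin channel Best2 rose by 3.44, the sodium pump regulator Fxyd4 by 3.23 and elastin, Eln, by 3.22. Casp14 and Depp1 each rose by 2.74. Tom1l2 and Tor1aip2 stood at least 6.30-fold and at least 4.28-fold higher than in controls below background. Of the falls, Mzb1, a chaperone of antibody-secreting cells, fell by 3.54 and Nxpe2 fell by 3.37. Id1 and Id4, inhibitors of differentiation, fell by 2.58 and fell by 2.57, Rhof fell by 2.49, and Pdrg1 was at least 3.81-fold lower and below background on both Nanog arrays. In all 19 genes the Nanog arrays lay wholly above or wholly below the controls, beside 33.3% by chance and 52.9% of the genes tested. Without control replicate 1, control replicate 2 or Nanog replicate 2 limma called 0 genes, with 733, 833 and 523 at an unadjusted p under 0.05. It called 11 without Nanog replicate 1, 49 without either intestine control array and 8 without either intestine Nanog array, 128 with the 4 colon arrays alone, 58 higher and 70 lower, 167 with array weights, 71 higher and 96 lower, and 11 higher against 11 lower in the authors' deposited values. With replicate 2 of both Nanog groups left out it called 0 genes in colon, with 513 at an unadjusted p under 0.05.

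8 genes were called in both tissues, each in the same direction: Csrp1, Fkbp5, Ddit4, Depp1, Fam107a, Tor1aip2 and Tom1l2 higher and Pdrg1 lower with Nanog. Fam107a is named here only because it is shared, a choice made after its values were seen. Independent sets of these sizes would share 0.0309 genes (hypergeometric exact test, one-sided, p = 3.03e-19). This p-value takes genes as independent draws and does not measure variation between animals. The 7 shared rises compare with 0.0181 for independent sets and the 1 shared fall with 0.00139. The comparisons use no array in common but share the estimate of spread. Across the 8607 genes, which are not independent replicates, the log2 fold changes of intestine and colon correlated with r = 0.524. The correlation was 0.439 and 0.445 between differences of replicates of the same number, and 0.302 and 0.265 between differences of opposite numbers. Tor1aip2 has a further probe above background on all 8 arrays, whose average log2 difference was 0.03, beside 3.04 for the tested probe. The other probes of Tom1l2 were below background on all 8 arrays. The number of shared genes was 0 without colon control replicate 1, colon control replicate 2 or colon Nanog replicate 2, and 3, 1 and 2 without intestine Nanog replicate 1, intestine Nanog replicate 2 and colon Nanog replicate 1.

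**Figure D2:**
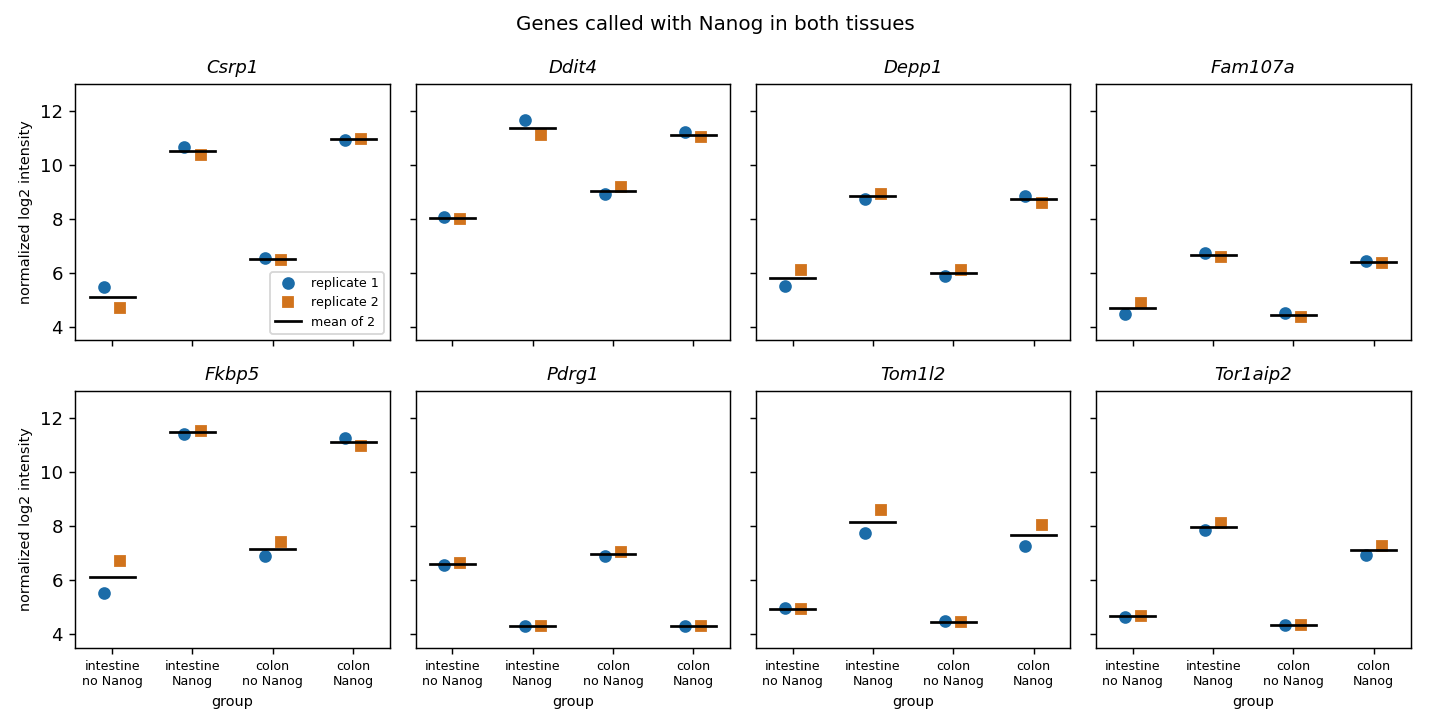
Normalized log2 intensity of the 8 genes called in both tissues, by group (points, replicate 1 as circles and replicate 2 as squares; bars, mean of the 2 arrays). In each of the 8 panels the 2 Nanog arrays of a tissue lie on the same side of both its control arrays, for Csrp1 with means of 5.08 without and 10.50 with Nanog in intestine and 6.51 and 10.94 in colon.

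Whether the effect of Nanog differed between colon and intestine was tested as an interaction. By limma 0 of 8607 genes passed, and 361 had an unadjusted p under 0.05, beside 430 expected by chance. The genes nearest the threshold were G6pc, with a log2 difference (colon effect minus intestine effect) of -3.37 ± 0.32 (SE, adjusted p = 0.1065), and Best2, with 3.21 ± 0.33 (adjusted p = 0.1065). Fxyd4 (2.84), Arg2 (4.15), Rgs16 (2.47) and Rnf186 (2.03) had positive differences, and Sult1a1 (-2.79), Nxpe2 (-3.47), Rgcc (-1.85) and Cidec (-2.56) negative ones, with adjusted p from 0.129 to 0.472. G6pc was below background on all colon arrays and Best2, Fxyd4 and Nxpe2 on all intestine arrays, so each of these 4 was measured in a single tissue and its difference is no measured contrast of 2 effects. Without intestine control replicate 1 the interaction called 20 genes, G6pc and Best2 among them (adjusted p = 0.0356 and 0.0452). Of the 34 gene lists, 6 passed camera with the preset correlation, each with a lower effect in colon than in intestine. These were interferon response, T cell, B and plasma cell, adipocyte, endothelium and smooth muscle genes, with median log2 differences from -0.26 to -1.80. With 1 array left out, camera no longer called B and plasma cell genes without colon control replicate 1 (adjusted p = 0.0713), adipocyte genes without intestine control replicate 2 (0.29), and smooth muscle genes without intestine control replicate 1 (0.298). It lost endothelial genes without that array, colon control replicate 1 or colon Nanog replicate 1 (up to 0.142). With all arrays their adjusted p was between 0.663 and 0.676 with an estimated correlation.

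Averaged over the tissues, 103 of 8607 genes changed with Nanog, 62 higher and 41 lower. The largest rises were in Lcn2, an iron-sequestering antimicrobial protein of inflamed epithelium, by 5.67 ± 0.83 log2 units (SE, adjusted p = 0.0347), Csrp1 by 4.92 ± 0.21 (adjusted p = 0.000539), Fkbp5 by 4.66 ± 0.28 (adjusted p = 0.00148), Pdk4, which restrains pyruvate oxidation, by 3.86 ± 0.52 (adjusted p = 0.0301), and Angptl4 by 3.32 ± 0.32 (adjusted p = 0.00811). Lcn2 was above background on 1 of 2 control arrays in each tissue. The largest falls were in Igsf9, with a log2 change of -3.68, in Dbp, a clock-controlled transcription factor, with -3.60, in Upk3b, a marker of mesothelium and urothelium, at least 4.20-fold and below background with Nanog, in Pdrg1, at least 3.14-fold, and in Mzb1 with -2.34. In 99 of the 103 genes the Nanog arrays of each tissue lay wholly above or wholly below its controls in the same direction, which chance gives for 5.6% of genes and which held for 14.9% of the genes tested. Csrp1, Fkbp5, Ddit4, Depp1, Tor1aip2 and Pdrg1 passed on average whichever single array was left out. Such fits do not check the probe itself. Csrp1 and Pdrg1 have 1 probe each, and the further Tor1aip2 probe above background on all 8 arrays had an average log2 change of 0.03. Leaving out single arrays gave between 6 genes (without colon control replicate 2) and 218, 103 higher and 115 lower (without intestine control replicate 2), with 170, 62 higher and 108 lower, without intestine control replicate 1, 48 and 27 without intestine Nanog replicates 1 and 2, 18 without colon control replicate 1, and 26 and 8 without colon Nanog replicates 1 and 2. With replicate 2 of both Nanog groups left out, limma called 0 genes, with 652 at an unadjusted p under 0.05, median scaling split 43 calls into 20 higher and 23 lower, the replicate number as a block 174 into 88 and 86, and the pancreatic covariate, chosen after seeing the data, 21 into 15 and 6.

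Transcription factors of the intestinal epithelium were shifted lower as a list by camera at its preset correlation, but not with an estimated correlation. Of 16 tested factors, 10 had lower and 6 higher values on average of the tissues (median -0.34, camera adjusted p = 0.0132, and adjusted p = 0.343 with an estimated correlation). Klf4, a factor of differentiated surface cells, fell by 1.66 ± 0.20 log2 units (SE, adjusted p = 0.0225). Cdx2, the master regulator of intestinal identity, had a change of -2.75 ± 0.49 that missed the threshold (adjusted p = 0.057), with -1.69 in intestine and -3.81 in colon, adjusted p = 0.561 and 0.0978. With the replicate number as a block Cdx2 passed on average (limma adjusted p = 0.0288). It passed on average without intestine control replicate 1 or 2 (adjusted p = 0.0389 and 0.0131) and in colon without either (0.0277), with an adjusted p up to 0.234 and 0.596 without other arrays. Hnf4a, a nuclear receptor of the absorptive lineage, had -0.91 (adjusted p = 0.111). All 9 tested genes of the Notch pathway, which maintains crypt progenitors and restrains secretory fate, had lower values (median -0.35, camera adjusted p = 0.00364, and adjusted p = 0.343 with an estimated correlation). Hes1, its main effector in the crypt, fell by 1.25 ± 0.19 (SE, adjusted p = 0.0391), and Nrarp had -1.19 (adjusted p = 0.137, and 0.0371 without intestine control replicate 2). Notch1, the receptor, had -0.29 (adjusted p = 0.636). Without any 1 of the 4 Nanog arrays or either colon control array, the adjusted p was 0.0516 to 0.117 for Klf4 and 0.0769 to 0.190 for Hes1.

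Genes of stem cells and proliferation went different ways. All 7 tested Wnt target genes had lower values with Nanog (median -0.73, or -0.56 with 1 gene at its bound, camera adjusted p = 0.00437, and adjusted p = 0.343 with an estimated correlation), among them Axin2, the feedback inhibitor of the pathway, with -1.54 and Ccnd1 with -1.52, neither past the threshold. Of 11 crypt stem cell genes 9 had lower values (median -0.56, or -0.45 with 1 gene at its bound, camera adjusted p = 0.00437, and adjusted p = 0.362 with an estimated correlation). Axin2, Cd44, Tnfrsf19, Ascl2 and Sox9 are in both the Wnt target and the crypt stem cell list, so these results are not independent. Olfm4, a stem cell marker of small intestine, had 0.45 in intestine (adjusted p = 0.813) and was below background in colon, Lgr5 and Myc did not pass the detection filter, and Muc2 and Mki67 are not on the array under these symbols. The 18 tested genes of DNA replication had a median of -0.44, or -0.37 with 2 at their bounds, with 13 lower and 5 higher (camera adjusted p = 0.00587, and adjusted p = 0.594 with an estimated correlation), and the replicative helicase subunit Mcm6 fell by 1.72 ± 0.21 (SE, adjusted p = 0.0225). All 11 tested genes of mitosis had higher values (median 0.46, camera adjusted p = 0.000152, and adjusted p = 0.427 with an estimated correlation), and the spindle protein Nusap1 rose by 1.40 ± 0.23 (SE, adjusted p = 0.0431). Of 11 targets of p53 8 had higher values (median 0.33, camera adjusted p = 0.0155, and adjusted p = 0.343 with an estimated correlation), with rises of Trp53inp1 by 1.66 and Pmaip1, an apoptosis inducer, by 1.47. Nusap1 and Trp53inp1 missed the threshold without any 1 of the 4 Nanog arrays or either colon control array (adjusted p up to 0.191 and 0.133). Mcm6 missed it without intestine Nanog replicate 2, colon control replicate 2 or either colon Nanog array (up to 0.123), and Pmaip1 without intestine control replicate 1, intestine Nanog replicate 2 or any colon array (up to 0.191).

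Further lists that camera called on average of the tissues went in both directions. Of 14 fibroblast and matrix genes 13 had higher values with Nanog (median 0.94, or 0.85 with 1 gene at its bound, camera adjusted p = 5.67e-07, and adjusted p = 0.362 with an estimated correlation). The collagen gene Col1a1 rose by 2.19 log2 units, Sparc by 1.59 log2 units and the collagen gene Col1a2 at least 1.62-fold. Of the 14 genes 10 passed when adjusted over the list alone, against 3 over all genes tested. All 8 B and plasma cell genes had lower values (median -1.60, or -1.38 with 2 genes at their bounds, camera adjusted p = 3.83e-06, and adjusted p = 0.343 with an estimated correlation), 7 of them past the threshold adjusted over the list alone and only Mzb1 over all genes tested. Among 12 antimicrobial and inflammatory genes of the epithelium 10 had higher values (median 2.24, or 1.91 with 5 genes at their bounds, camera adjusted p = 0.00874, and adjusted p = 0.403 with an estimated correlation), with Lcn2 the single one to pass. Single arrays carry much of this median, which was 0.74 without colon Nanog replicate 2, 0.435 without replicate 2 of both Nanog groups and 0.90 with the pancreatic covariate (camera adjusted p = 0.189). Reg2 of the list had a mean of 8.98 ± 5.75 (SD, n = 2) in intestine and 8.90 ± 5.44 (SD, n = 2) in colon with Nanog. This list's rise was not separated from the pancreatic signal. Of 15 enteroendocrine genes 12 had higher values (median 0.39, camera adjusted p = 0.00874, and adjusted p = 0.362 with an estimated correlation), and Chga, the granule protein of hormone-secreting cells, rose by 1.64 ± 0.21 (SE, adjusted p = 0.0283). Of 12 immediate early and heat shock genes 10 had lower values (median -0.74, camera adjusted p = 0.00236, and adjusted p = 0.362 with an estimated correlation), such as Egr1 with -1.60 and Junb with -1.64, neither past the threshold in the main fit. Junb passed on all arrays with the replicate number as a block (limma adjusted p = 0.0366). Egr1 passed without intestine control replicate 1 (adjusted p = 0.045) and Junb without intestine control replicate 2 (0.0402). Col1a1, Sparc and Chga missed the threshold without any 1 of the 4 Nanog arrays or either colon control array (adjusted p up to 0.162, 0.186 and 0.138), and Mzb1 without any colon array (up to 0.0984). Col1a2 kept its call only without intestine control replicate 2 (otherwise up to 0.208), and Lcn2 only without that array or colon Nanog replicate 1 (otherwise up to 0.154).

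In all, camera called 17 of 34 lists on average of the tissues, 7 higher and 10 lower. Other divisions of the 8 arrays gave a median of 9 lists and at most 15 by the same test. A call by camera at the preset correlation therefore does not by itself tie a list to Nanog. Among the called lists not given above, adipocyte genes had a median of -0.79 over 6 genes (-0.76 with 2 at their bounds), cholesterol synthesis genes -0.49 over 13, T cell genes -0.40 over 9 and erythroid genes 1.64 over 2. Their camera adjusted p was 0.00405, 0.0155, 0.0497 and 0.0224, and their adjusted p 0.362, 0.555, 0.555 and 0.362 with an estimated correlation. With 1 array left out, camera lost the average call of crypt stem cell and erythroid genes without intestine control replicate 2 (adjusted p = 0.0535 and 0.0745). The same held for DNA replication genes without colon control replicate 2 (0.124) and enteroendocrine genes without colon control replicate 1 (0.0565). It lost antimicrobial genes without intestine Nanog replicate 2 or colon control replicate 1 (up to 0.0687). Cholesterol synthesis genes were lost without intestine Nanog replicate 2 or colon control replicate 2 (up to 0.128). It lost pancreatic genes without intestine control replicate 1 or replicate 2 of either Nanog group (up to 0.192). T cell genes were lost without replicate 1 of any group but colon with Nanog, or without colon Nanog replicate 2 (up to 0.235). In intestine camera called 11 lists and in colon 18, and with an estimated correlation it called 0 of the 34 lists in intestine, in colon, in their average and in their difference. The rotation test fry, which asks whether a list's genes move one way on balance, called 0 lists in intestine, 2 in colon (Notch pathway and intestinal transcription factors) and 6 on average of the tissues (those 2, B and plasma cell, Wnt target, p53 target and pluripotency genes). The 3 tested pluripotency genes, Tbx3, Klf2 and Dppa5a, had lower values on average (median -0.54, fry adjusted p = 0.0458, camera adjusted p = 0.0663, and adjusted p = 0.362 with an estimated correlation), 0 of them past the threshold singly. Of the fits with 1 array left out camera called the list in that without intestine control replicate 1. Beyond these 17 lists camera called myeloid genes in intestine (median 0.55, camera adjusted p = 0.0194, and adjusted p = 0.621 with an estimated correlation). That call was lost without intestine control replicate 1 or either intestine Nanog array (up to 0.785). In colon it called interferon response genes (median -0.98, camera adjusted p = 0.00335) and endothelial genes (median -0.32, camera adjusted p = 0.0359), with an adjusted p of 0.507 for each with an estimated correlation. Interferon response genes lost their call without colon control replicate 1 and with the pancreatic covariate (median -0.265, camera adjusted p = 0.242). Endothelial genes lost theirs without colon control replicate 1 or colon Nanog replicate 1. The 17 lists not called on average, with camera adjusted p from 0.0663 to 0.881, were pluripotency, myeloid, Paneth, tuft, bile acid and xenobiotic, goblet, interferon response, squamous, dietary lipid, brush border, colonocyte and posterior Hox, endoplasmic reticulum stress, endothelium, enteric neuron and glia, oxidative phosphorylation, smooth muscle, and fetal-like and YAP target genes.

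**Figure D3:**
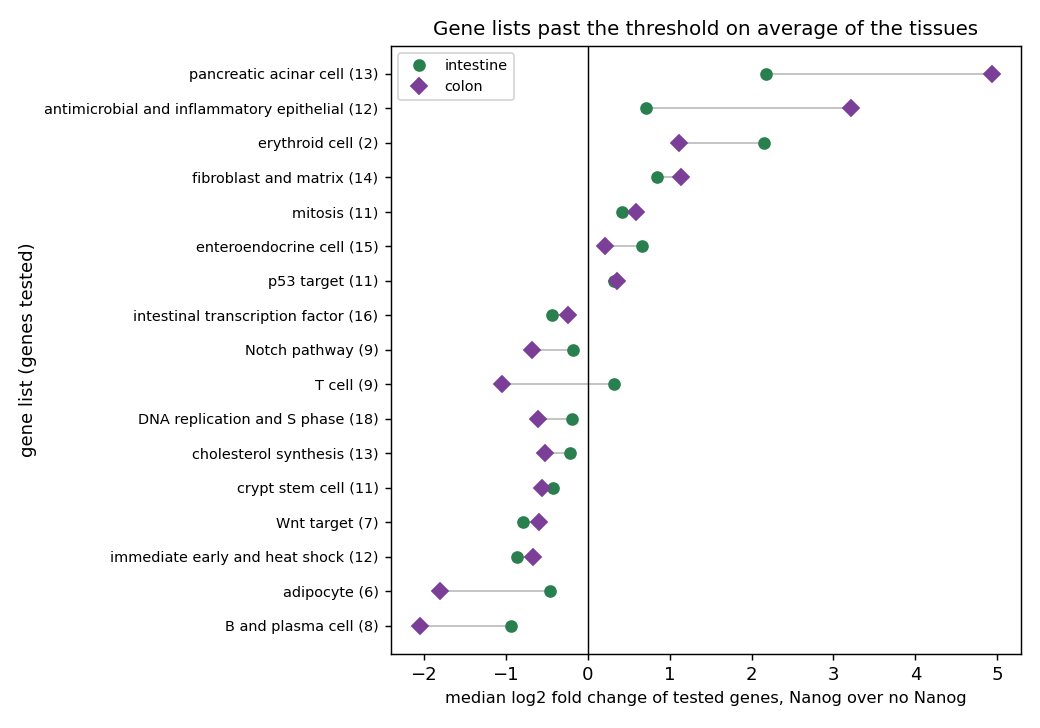
Median log2 fold change, Nanog over no Nanog, of the tested genes of the 17 lists that camera called on average of the tissues, in intestine (circles) and colon (diamonds), with the number of genes tested in brackets. T cell genes have medians of 0.32 in intestine and -1.05 in colon, and pancreatic acinar genes have the highest median, 4.93, in colon.

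Without Nanog, colon and intestine differed in 473 of 8607 genes, 210 higher and 263 lower in colon. Genes of dietary lipid handling stood lower in colon in 12 of 13 cases (median -4.86, or -4.53 with 6 genes below background at their bounds, camera adjusted p = 4.46e-16, and adjusted p = 0.132 with an estimated correlation). The apolipoproteins Apoa1 and Apoa4 were at least 613-fold and at least 401-fold lower in colon and below background on both its arrays. Brush border enzymes followed, 13 of 14 lower (median -3.00, camera adjusted p = 1.46e-12, and adjusted p = 0.272 with an estimated correlation), with sucrase-isomaltase, Sis, at least 302-fold and trehalase, Treh, at least 140-fold lower. Of 10 tested Paneth cell genes 9 were lower in colon (median -4.95, or -4.31 at bounds, camera adjusted p = 6.94e-07, and adjusted p = 0.434 with an estimated correlation), such as the defensin Defa20, at least 545-fold, whereas Mptx1 was 6.68 log2 units higher. The Paneth cell median lay between -5.43 and -1.95 with 1 array left out. Olfm4 was at least 35.4-fold lower. In the other direction, all 12 colonocyte and posterior Hox genes were higher in colon (median 2.52, or 2.44 with 4 genes at their bounds, camera adjusted p = 2.78e-10, and adjusted p = 0.0442 with an estimated correlation), among them the proton pump Atp12a, at least 131-fold, and the water channel Aqp8, by 6.89 ± 0.76 (SE, adjusted p = 0.00331) and above background on 1 of the 2 intestine arrays without Nanog. Bile acid and xenobiotic genes were lower in 14 of 16 cases (median -2.95, camera adjusted p = 4.01e-09, and adjusted p = 0.0442 with an estimated correlation), and the hormone gene Insl5 was at least 36.2-fold higher in colon. Among the rises outside these lists were Hao2, at least 56.1-fold, Tgm3, at least 43.4-fold, and Hsd11b2, by 5.40 log2 units.

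Fibroblast and matrix genes were also higher in colon without Nanog (median 1.26, camera adjusted p = 2.03e-05, and adjusted p = 0.571 with an estimated correlation), as were myeloid genes (median 1.12, camera adjusted p = 0.0021, and adjusted p = 0.571 with an estimated correlation). Camera also called mitosis genes (median -0.40) and tuft cell genes (median -0.89) lower, and smooth muscle genes (median 0.71) and B and plasma cell genes (median 0.79, or 0.73 with 1 gene at its bound) higher in colon. Their camera adjusted p was 0.015, 0.0418, 0.017 and 0.0473, and their adjusted p 0.63, 0.434, 0.571 and 0.621 with an estimated correlation. With 1 array left out, camera lost myeloid and smooth muscle genes without intestine control replicate 1 (adjusted p = 0.0606 and 0.103), and mitosis genes without that array or colon control replicate 1 (up to 0.432). It lost B and plasma cell genes without intestine control replicate 2 or colon control replicate 1 (up to 0.543), and tuft cell genes without any array except intestine control replicate 1 and the colon Nanog arrays (up to 0.157). The comparison of the tissues called 779 genes without intestine control replicate 2, 142 and 140 without colon control replicates 1 and 2, 252 without either colon Nanog array and 189 with the 4 control arrays alone. Median scaling gave 127 higher and 244 lower.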

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

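Tests of 34 lists were planned before the data were examined. The 6 lists given here are those whose effect of Nanog differed between colon and intestine by camera at the preset correlation, so they were picked by that result. No group holds enough arrays to test for a single outlying array.

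Interferon response genes had a median effect of 0.33 log2 units in intestine and -0.98 in colon, a median difference of -1.19 (camera adjusted p = 6.5e-06), with all 13 genes lower in colon. This difference lay between -1.995 and -0.464 with 1 array left out and was -0.594 with the pancreatic covariate. T cell genes had medians of 0.32 and -1.05 and a difference of -1.23 (camera adjusted p = 1.2e-05), with all 9 genes in the same direction. B and plasma cell genes, with medians of -0.93 and -2.05, differed by -0.95 over 8 genes (camera adjusted p = 0.000317). Adipocyte genes, with -0.46 and -1.80, differed by -1.80 over 6 genes (camera adjusted p = 0.0013). Endothelial genes, with 0.24 and -0.32, differed by -0.47 over 11 genes (camera adjusted p = 0.00422). Smooth muscle genes, with 0.31 and -0.08, differed by -0.26 over 14 genes (camera adjusted p = 0.00822). With an estimated correlation the adjusted p was 0.663 for the first 4 lists and 0.676 for endothelial and smooth muscle genes, and by fry it was 0.761 or 0.795, so none of the 6 passed either of these tests.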

How the results depend on the processing

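The fits without the 2 Nanog arrays highest in pancreatic genes and with the pancreatic covariate were chosen after the data were seen, and all other settings before. The called genes kept their sign in every setting that tested them. Over the genes examined one by one, 2326 values kept direction and side of the threshold, 726 were no longer past it, 36 came past it and 2 reversed. Over the lists that passed the main test and the pluripotency list, 1245 did, 248 were no longer past it, 5 came past it, all of the pluripotency list, and 3 reversed, and other lists that did not pass were not counted. The 2 reversed gene values are Olfm4 in intestine, with -0.05 under median scaling and -0.126 without intestine control replicate 1, the lowest of a range up to 1.02 with 1 array left out. The pancreatic list reversed on average without the 2 arrays (-0.293) and with the covariate (-0.055), and in colon with the covariate, where the median of 0.149 and the test differ in sign. Since the 2 arrays were chosen by this list and the covariate is its own mean, the loss of its rise was fixed in advance. Median scaling moved the median of all genes by -0.369 in intestine, 0.415 in the difference, -0.159 on average, 0.041 in colon and -0.091 between the tissues.

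The intestine count of 14 was 6 with detection on all 8 arrays, 24 with trend and robust estimation, 9 with array weights, 0 with the 4 arrays alone, 0 without the 2 arrays, and 2 to 71 with 1 array left out. The colon count of 19 was 7 without a filter, 12 with detection on all arrays, 167 with array weights, 128 with the 4 arrays alone, 0 without the 2 arrays, 5 with the covariate, and 0 to 49 with 1 array left out. The difference count of 0 was 3 without background correction, 3 with an offset of 50, and 0 to 20 with 1 array left out. The average count of 103 was 43 with median scaling, 48 without a filter, 174 with the replicate number as a block, 0 without the 2 arrays, 21 with the covariate, and 6 to 218 with 1 array left out. The tissue count of 473 was 302 without a filter, 287 with detection on all arrays, 189 without the 2 arrays, 189 with the 4 control arrays alone, and 140 to 779 with 1 array left out. The overlap of 8 was 4 with the authors' values, 3 without a filter, 3 with detection on all arrays, 0 without the 2 arrays, 3 with the covariate, 77 at an unadjusted p under 0.01, and 0 to 12 with 1 array left out. The Nanog probe in colon moved from -0.05 to -0.22 in the authors' values, and lay between -0.152 and 0.057 with 1 array left out.

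Lists called in intestine, 11, were 6 without a filter, 0 with an estimated correlation, 0 by fry and 5 to 11 with 1 array left out. In colon the 18 were 0 with an estimated correlation, 2 by fry and 10 to 17 with 1 array left out. In the difference the 6 were 12 with median scaling, 11 with the block, 12 without the 2 arrays, 0 with an estimated correlation, 0 by fry and 7 to 14 with 1 array left out. On average the 17 were 0 with an estimated correlation and 6 by fry, and between the tissues the 11 were 2 with an estimated correlation. The cause of these moves was not tested, except that fits without arrays have fewer of them and detection on all arrays tests 6648 genes.

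A replicate number was not taken as a pair, since the labels do not say that it marks an animal or a batch. Deviations of replicates from their group mean correlated across genes by 0.113 to 0.468 between groups. With the block the counts were 19 in intestine, 18 in colon, 0 in the difference and 538 between tissues, and Cdx2 and Junb, which missed the threshold on average, passed with an adjusted p of 0.0288 and 0.0366. A block by slide was not run, since the column names give no slide. With 1 array left out, the lone array of a group was assumed to vary like the other groups. Signal near background limits folds to bounds.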

Other observations

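Of the tests in this part, those of Nanog expression in gut cells, of a batch of the arrays numbered 2, of the pancreatic covariate, of genes called without the other 2 Nanog arrays, of a genetic difference and of 1 segment behind all 4 genes were chosen after the result was seen, as were the added gene lists and the genes named in the next paragraphs.

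Of the genes called on average of the tissues, 13 are named here one by one, as single genes and not as a tested group. Id1 fell by 2.18 ± 0.20 log2 units (SE, adjusted p = 0.00676), Id4 fell by 2.11, Id3 fell by 1.29, Smad6 fell by 1.68 and Ihh fell by 1.60. Without colon control replicate 2 or colon Nanog replicate 2 the adjusted p of Id1 was at most 0.0508 and that of Id4 at most 0.0503, and those 2 genes passed in the other 6 fits with 1 array left out. Id3 and Ihh passed only without either intestine control array (otherwise up to 0.143 and 0.142), and Smad6 only without either of these or intestine Nanog replicate 1 (otherwise up to 0.113).

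Elastin rose by 2.56, Mfap4 by 2.05, Col4a2 by 1.27 and Nid1 by 1.22. The mast cell protease Cpa3 rose by 2.41, the sterol hydroxylase Cyp27a1 by 2.26 and the nuclear receptors Nr5a2 and Nr1h4 by 1.20 and 1.11. With 1 array left out, Nr1h4 kept its call in 0 of 8 fits, Cpa3 in 1 (without intestine control replicate 2), Mfap4 in 3 (without that array, intestine control replicate 1 or intestine Nanog replicate 2) and the other 5 in 2 (without either intestine control array), with an adjusted p up to 0.0887 for Eln, 0.142 for Mfap4, 0.208 for Col4a2, 0.203 for Nid1, 0.191 for Cpa3, 0.162 for Cyp27a1, 0.146 for Nr5a2 and 0.195 for Nr1h4.

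The 103 genes called on average exceeded every other grouping of the arrays, of which 34 of 35 could be fitted. Only 1 of the 34, the real one, gave as many, and the highest other gave 25 genes. The 34 include divisions that, unlike the real one, split a tissue's arrays unequally, so their share does not exclude a random division. For lists, 1 of 34 gave 17, the highest other 15 and the median other 9, beside a median of 0 genes. Of these divisions 18 put 2 arrays of each tissue on either side, too few for a share under 5%, and the highest other among them also gave 25 genes and 15 lists. Arrays of the same number deviated together (correlations of 0.113 to 0.468 between groups), so it is not known that the arrays can be freely exchanged, and the 8 divisions that part the arrays of the same number in each tissue are too few as well, with 0 genes and 15 lists as the highest other. The split by replicate number gave 9 genes and 8 lists.

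Pancreatic acinar genes differed between the arrays of every group, and Nanog expression in gut cells as the sole source is argued against by a control array lying 4.7 log2 units above a Nanog array of its tissue. Further pancreatic genes outside the list followed it over the 8 arrays (r = 0.982, exact permutation p = 9.92e-05, two-sided; rho = 0.976, p = 0.000397; r = 0.966 without the 2 farthest arrays; 1 relation computed), although Sycn, Spink1 and Dmbt1 among them were high on all colon arrays, and Prss2 and Clps of the list reached 14.13 and 14.40 on replicate 2 of intestine with Nanog, so pancreatic tissue carried along at dissection is a candidate source. A dissection or batch shared by the arrays numbered 2 cannot be told apart from it, since replicate 2 is higher in 4 of 4 groups. Whether such tissue is the whole cause of the called genes could not be decided by leaving out arrays. Calling favours genes whose replicates resemble each other, so a small loss was likely in advance. Without the 2 Nanog arrays highest in pancreatic genes the 103 kept a median 0.993 of their log2 change (interquartile range 0.941 to 1.07, 0 genes under 0.5). Without the other 2 Nanog arrays they kept 1.007. The 13 genes called without those other arrays, 4 of them among the 103, kept a median 0.216 without the 2 highest in pancreatic genes. Their interquartile range was 0.103 to 0.772. They had been called on the very Nanog arrays then left out, so a loss was likely here too. The acinar list kept -0.083, a loss fixed in advance because the 2 arrays were chosen by this list. The calls themselves did not all stand, with 0 left on fewer arrays without those 2 and 21 with the list's mean as a covariate, 20 of them among the 103, where the other 83 had a median absolute change of 1.47 (median SE 0.21) before and 1.40 (0.24) after at 3 residual degrees of freedom instead of 4, and a part of such tissue in single changes stays open.

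Fkbp5, Tsc22d3, Sgk1, Ddit4, Pdk4 and Angptl4 were higher and Dbp and Per2 lower with Nanog, of which Tsc22d3, Sgk1, Pdk4 and Dbp missed the threshold without any 1 of the 4 Nanog arrays or either colon control array (adjusted p up to 0.113, 0.149, 0.14 and 0.137), Per2 without any 1 of the 8 (up to 0.204) and Angptl4 without either colon control array or colon Nanog replicate 2 (up to 0.0645). Glucocorticoid-induced genes not among the called genes had a median of 0.476 over 14 genes (camera p = 0.000263, and p = 0.0178 with an estimated correlation). Of these 11 were higher, whereas Klf9, Bcl6 and Usp2, which is also in the clock list, were lower. Glucocorticoid exposure may thus contribute. The p-values of this and the following added lists are unadjusted. Clock genes in phase with Dbp minus those in antiphase gave -1.66 (camera p = 0.0131 and 0.0033, and p = 0.267 and 0.0406 with an estimated correlation), with Cry2 and Clock against that direction, so harvest at another time of day may contribute too. Fasting genes had a median of 0.267 with a camera p of 0.128, which leaves fasting open. An effect of Nanog itself is also open and was not tested apart from these.

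Csrp1, Tor1aip2, Tom1l2 and Pdrg1 were each read by 1 probe above background, except that Tor1aip2 has another. A genetic difference between the animals at the probe could give such calls: the ratio of the other probe's change to the tested one's was 0.009 for Tor1aip2, beside a median of 0.844 over 21 called genes with other probes. With 1 gene of the 4 testable, and splice forms also able to give this, it cannot be told apart from a change in expression. A single segment carried with a transgene as the cause of all 4 is argued against, since they lie on 3 chromosomes with 0 pairs within 20 tested genes. A segment behind part of them stays open, since 32 pairs of called genes lay within 20 tested genes of each other, beside a median of 24 and a 95th percentile of 32 in random sets.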
